A study of Mus musculus with 44 samples.

How the data were processed

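C2C12 cells, a mouse myoblast line that stops dividing and fuses into myotubes when serum is lowered, were profiled on Illumina bead arrays while they grew (day 0) and during differentiation. Per the labels' protocols, cell lysates were incubated with beads coated with an antibody against AUF1 or with control IgG, and the RNA recovered with the beads (RNA immunoprecipitation, called pulldown here) was purified after DNase and proteinase treatment. Input RNA is RNA of the same cell line without pulldown. The titles of the input samples speak of input DNA while their descriptions and molecule field give RNA, and they were treated as RNA. The label protocol amplifies RNA with an oligo-dT primer and labels it with biotin. The groups were AUF1 pulldown on days 0 (4 arrays), 2 (3), 4 (3) and 6 (4), IgG pulldown on days 0 (4), 2 (3), 4 (4) and 6 (4), and input on days 0, 3 and 6 (5 each), 44 arrays in all.

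The deposited table holds, per the file headers, a signal intensity that was not normalized and a detection p-value for each of 25697 probes on each array. The submitters' processing notes name GenomeStudio 1.6.0. Whether background was subtracted is not given in the sources used here; the lowest signal on any array was 32.4, and the correction below was therefore applied to every array. All 44 signal columns were used and no 2 of them held identical values (0 identical pairs). Column names give the group, an experiment number from 1 to 4 and an array number. The experiment numbers run differently from the replicate numbers of the titles in some groups, so columns were assigned to groups and not to single samples.

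The table names probes by Illumina identifier alone. The sources used here do not pair these probes with genes: 0 of the 25697 identifiers occur in the gene table at hand. All tests were therefore made on probes, in place of 1 probe per gene as planned, and the gene lists, cell type markers and individually chosen genes fixed before the data were examined are not analysed here. Probes named in the text are, for each comparison, up to 2 with the highest and 2 with the lowest log2 change among those with adjusted p under 0.05 whose change had the same sign on every array of the first group against the mean of the second group of that day. The rule fixed before the data were examined named more genes per comparison; it was narrowed to 2 and 2 when it was known that no gene names could be given, before the values of these probes were seen.

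Signals were processed with limma 3.58.1 in R 4.3.3. Background was corrected by the normal-exponential model, with negative-control means and spreads inferred from the detection p-values, 16 was added, and values were quantile normalized and taken to log2 (neqc). This was done separately for the 29 pulldown arrays, the 15 input arrays, and the 18 AUF1 and input arrays of days 0 and 6. Probes with a detection p-value under 0.05 on at least 3 arrays of a fit were tested: 13812, 13750 and 14005 probes. Each fit had a mean per group and 1 spread per probe shared by its groups (lmFit, contrasts, eBayes), and p-values were adjusted over all tested probes by Benjamini-Hochberg, with calls at adjusted p under 0.05. Quantile normalization gives every array of a fit the same distribution, so a change of total RNA is not measured and higher and lower are relative to the other probes. Where every array of the dimmer group was at detection p of 0.05 or more, the fold is a bound: the bright group's mean against the mean of, per array, the higher of the probe's value and the lowest value of a detected probe.

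Comparisons were AUF1 against IgG pulldown per day and as the mean of 4 days, the change of that difference from day 0 to day 6 and over all days (an F test), input on days 3 and 6 against day 0 and against each other, and AUF1 pulldown against input on days 0 and 6. The experiment number was checked as a pairing of AUF1 and IgG arrays: across probes, the deviations of same-numbered arrays from their group means correlated at 0.26 to 0.77 on day 0, 0.11 to 0.48 on day 2 and 0.16 to 0.84 on day 6, each over 0.1, and the numbers were taken to pair these arrays. On day 4 the lowest of 3 correlations was -0.09, and between AUF1 and input arrays they ran from -0.22 to 0.03 on day 0 and from -0.02 to 0.07 on day 6; there the numbers were not taken as pairs. Detected share and mean signal were compared by exact permutation within days and, added after the data were examined, by exact permutation of the signs of the paired differences. The limit of 0.1 was fixed beforehand, but the counts with the block were seen together with these correlations. Pulldown arrays of different numbers were not set beside these values. Input arrays of different number and day correlated at up to 0.51, so a value over 0.1 does not establish a pair. The pairing, and each result that uses it, rests on this assumption. The planned fit holds no pairs, so probe counts and limma p-values ignore the pairing unless a block is named. Input arrays of 1 day and the same experiment number correlated at -0.42 to 0.56 (3 pairs) and were kept as separate arrays. Nothing in the labels says that arrays of a group come from separate cultures, so p-values measure only the spread between these arrays, which may be technical. For overlaps between comparisons that share the same arrays, the value expected with no effect was simulated from the fitted spread, and the shared arrays were also divided between the comparisons in 20 ways.

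The steps were tested on simulated arrays with 66 or 67 changed probes per size of change, taken from the brighter ones. For AUF1 against IgG on day 0, 22.4% of probes changed by 1 log2 unit and 78.8% of those changed by 2 were recovered; on day 2 these were 11.9% and 54.5%, and on day 6 26.9% and 63.6%. For input on day 6 against day 0, 73.1% and 98.5% were recovered, and for AUF1 against input on day 0, 40.3% and 89.4%. Between 2 and 10 unchanged probes were called per simulation of 14283 to 16690 probes. The simulated noise was independent between probes and arrays. Real arrays deviated together, as the correlations of same-numbered arrays show, so recovery and false calls may differ in the real data. The number of arrays limits the precision. Alternatives chosen before the data were examined were median scaling, scaling by mean and SD, no background correction, no detection filter or a stricter one (detection p under 0.01), trend and robust moderation, a fit of only the groups compared, the experiment number as a replicate block, and leaving out each array in turn. Alternatives added after seeing the data were the experiment number as a block across days, the detected share of each array as a covariate, array weights, leaving out arrays with under 30% of probes detected, and sets of 3 input array numbers as a block.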

Results

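RNA recovered with AUF1 from differentiating C2C12 myoblasts was measured on 14 arrays, RNA recovered with control IgG on 15 and input RNA on 15. AUF1 (gene Hnrnpd) is an RNA-binding protein that binds AU-rich elements of many mRNAs. The pulldowns were made to find the mRNAs bound by AUF1 as myoblasts become myotubes, and the IgG arrays measured what the beads and a control antibody recovered. Probes could not be paired with genes here, so results are given for sets of probes and for a few probe identifiers.

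Fewer probes were detected on pulldown arrays than on input arrays, and AUF1 arrays were dimmer than IgG arrays. On input arrays 46.9% ± 1.17 (SD, n = 15) of the probes were detected, on IgG arrays 41.6% ± 5.83 (SD, n = 15) and on AUF1 arrays 35.2% ± 6.74 (SD, n = 14). The mean signal was 257 ± 43.4 (SD, n = 15) on input, 262 ± 80.4 (SD, n = 15) on IgG and 167 ± 63.2 (SD, n = 14) on AUF1 arrays. Averaged over the 4 days, the detected share of AUF1 minus that of IgG was -6.94 percentage points (exact permutation within days, two-sided p = 0.00809; adjusted p = 0.0405 over 5 comparisons) and the difference in mean signal was -99.6 (p = 0.00136; adjusted p = 0.0068). On single days the detected share differed by -5.29 points on day 0, -11.5 on day 2, -7.77 on day 4 and -3.19 on day 6, with exact permutation p from 0.1 to 0.314. On day 2, where 3 arrays stood against 3, 0.1 is the smallest p possible. These tests do not use the pairing by experiment number. In pairs, a test added after the data were examined, the AUF1 array had the lower detected share and the lower mean signal in all 11 pairs of days 0, 2 and 6, with mean differences of -6.22 points ± 4.78 (SD, n = 11) and -80.5 ± 56.3 (SD, n = 11). The exact permutation of signs gave a two-sided p of 0.000977 for each (adjusted 0.000977), the smallest it can give. The 11 pairs carry only 4 experiment numbers, each found on more than 1 of these days, and the test counts every pair as independent. If pairs of the same number are related, this p is too small. On day 4, where the numbers were not taken as pairs, AUF1 was also lower in 3 of 3 arrays of the same number. Within single days the smallest p of the paired test is 0.125 with 4 pairs and 0.25 with 3.

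**Figure D1:**
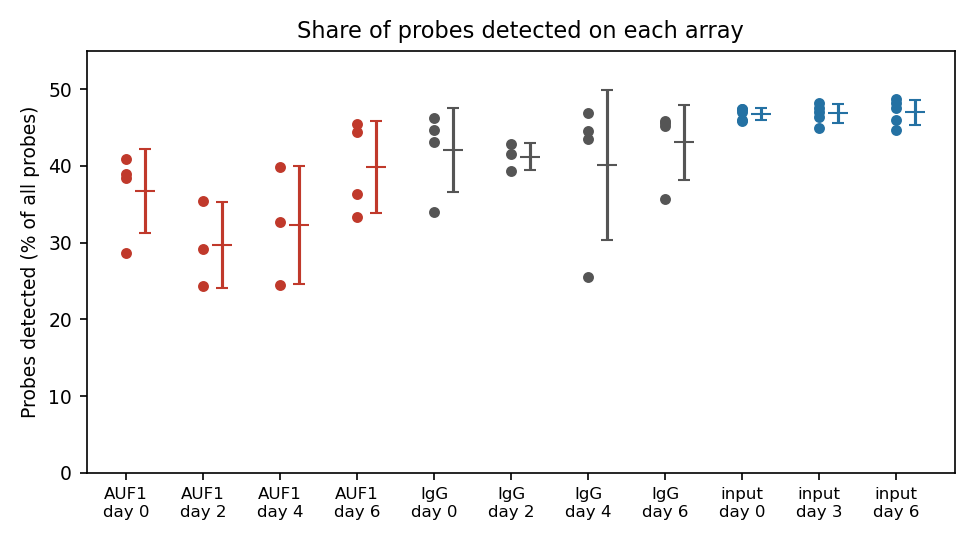
Percent of the 25697 probes detected (detection p under 0.05) on each array, by group; points are arrays, and the bars beside them are the mean ± SD. The 15 input arrays lie between 44.7% and 48.7%, and the 14 AUF1 arrays between 24.4% and 45.5%.

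The comparison of AUF1 with IgG pulldowns asked which RNAs AUF1 recovered beyond the control. Averaged over the 4 days, 2919 of 13812 probes differed (21.1%): 1288 were higher in AUF1 and 1631 lower. Differences of at least 2-fold were mostly downward, with 29 such probes higher and 307 lower, and the median size among the called probes was 0.61 log2 units. The highest were ILMN_2942573, higher by 1.29 ± 0.27 (log2, SE; adjusted p = 0.00183), and ILMN_2945095, higher by 1.27 ± 0.29 (adjusted p = 0.00402). Each was higher in AUF1 in 14 of 14 pairs of the same day and experiment. The pairs include day 4, where the numbers were not taken as pairs. The rule for naming probes by sign also favours such counts. The IgG array of experiment 2 on day 4, with 25.6% of probes detected, has no AUF1 partner and is in no pair. It stood at 7.52 and 8.23 (log2) for these probes, against AUF1 means of 7.51 and 7.62 on day 4. The IgG array of experiment 3 on day 6 (35.7% detected) stood at 7.65 and 7.48, against AUF1 means of 7.37 and 7.26. These probes were thus as high on these IgG arrays as with AUF1. Under median scaling these probes were higher by 0.32 and 0.22 and were not called (adjusted p = 0.230 and 0.242, the highest over 40 alternatives, where the lowest were 2.0e-06 and 3.3e-06). The lowest were ILMN_2901944, with a difference of -2.44 ± 0.31 (adjusted p = 2.2e-05), and ILMN_2730425, with -2.24 ± 0.27 (adjusted p = 1.4e-05). Each was lower in 13 of 14 pairs. With the experiment number as a replicate block 6538 probes were called, 3148 higher and 3390 lower, and these held all 2919. Median scaling shifted the AUF1 minus IgG differences by a median of -0.56 (log2) and gave 143 higher and 6637 lower, and scaling by mean and SD gave 1428 and 2833; of the 2919 probes, 2431 kept their direction relative to the median shift under median scaling.

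**Figure D2:**
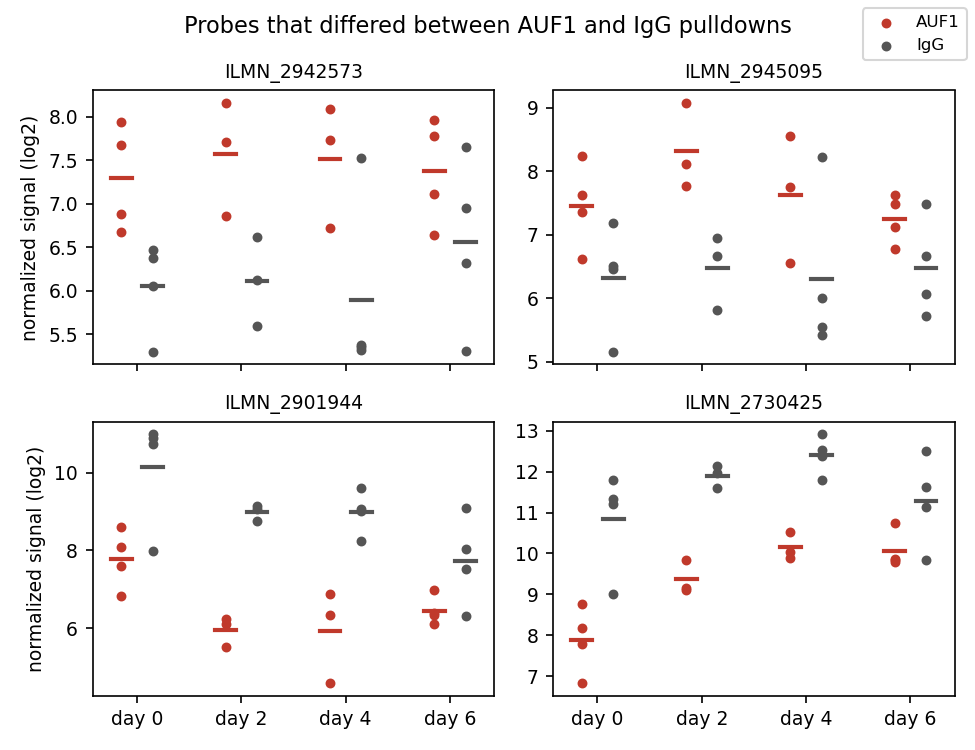
Normalized log2 signal of the 4 named probes on each pulldown array, by day; red points are AUF1 arrays, grey points IgG arrays, and horizontal lines group means. ILMN_2942573 and ILMN_2945095 were higher with AUF1 by 1.29 and 1.27 on average over the days, and the differences of ILMN_2901944 and ILMN_2730425 were -2.44 and -2.24.

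On day 0, in growing cells, 20 probes differed in the planned fit without pairs, and each was lower in AUF1. With the replicate block, which uses the pairs, 1764 probes were called, 896 higher and 868 lower. The downward direction of the 20 therefore does not hold for the larger set. ILMN_2730425 stood at 7.89 ± 0.81 (log2, SD, n = 4) with AUF1 and 10.83 ± 1.25 (n = 4) with IgG, a difference of -2.94 ± 0.51 (SE; limma adjusted p = 0.0133). ILMN_3128792 differed by -2.74 ± 0.39 (adjusted p = 0.00356). Their calls were lost under 6 and 2 of 20 alternatives (adjusted p up to 0.215 and 0.178). A fit of the day 0 arrays alone or median scaling (median shift -0.36) called 0, with 1716 and 1817 at an unadjusted p under 0.05. Without background correction 15 were higher and 43 lower. Leaving out 1 array at a time, the count was 12, 13 and 7 without the AUF1 arrays of experiments 1, 3 and 4, and 1, 2, 6 and 223 without the IgG arrays of experiments 1, 2, 3 and 4.

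On day 2, after the change to differentiation medium, 294 probes differed, 80 higher and 214 lower in AUF1. ILMN_2666061 was higher by 2.26 ± 0.61 (log2, SE; adjusted p = 0.0496) and ILMN_2855551 by 2.11 ± 0.46 (adjusted p = 0.0249), the latter being detected on 1 of 3 IgG arrays. ILMN_2735735 was not detected on any of the 3 AUF1 arrays and was at least 4.15-fold lower than with IgG (adjusted p = 0.0239). ILMN_2797584 differed by -3.08 ± 0.47 (adjusted p = 0.00634) and was detected on 1 of 3 AUF1 arrays. Of 18 alternatives, ILMN_2666061 lost its call under 10, with a change down to 0.56 and adjusted p up to 0.729. The other probes, in the order given, lost theirs under 6, 5 and 3 (adjusted p up to 0.179, 0.215 and 0.137). The replicate block gave 3614 calls (1579 higher and 2035 lower), a fit of the day 2 arrays alone 28, median scaling 0 higher and 2141 lower (median shift -0.85), scaling by mean and SD 344 and 1024 (median shift -0.12), and leaving out the arrays with under 30% of probes detected 0 (1881 at an unadjusted p under 0.05), with 1 AUF1 array left that is assumed to vary like the other groups. Without the AUF1 arrays of experiments 1, 2 and 4 in turn the count was 116, 1 and 500, and without the IgG arrays of experiments 1, 2 and 4 it was 0 (limma; 1716 at an unadjusted p under 0.05), 4 and 692.

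On day 4, 95 probes differed, 38 higher and 57 lower in AUF1. ILMN_1212702 was higher by 1.84 ± 0.42 (log2, SE; adjusted p = 0.0452) and ILMN_1215893 by 1.82 ± 0.37 (adjusted p = 0.0309), the latter turning to -0.077 under median scaling, which shifted the median of all probes by -0.73; relative to that shift all 95 called probes kept their direction. ILMN_2901944 differed by -3.06 ± 0.64 (adjusted p = 0.0363) and ILMN_2416670 by -2.77 ± 0.46 (adjusted p = 0.0118). Of 19 alternatives, ILMN_1212702 lost its call under 9, with a change down to 0.23 and adjusted p up to 0.745. ILMN_1215893 kept its direction but lost its call under 5 others, and the lower probes lost theirs under 6 and 2 (adjusted p up to 0.301 and 0.216). The replicate block, although the numbers were not taken as pairs here, gave 3398 calls, and array weights gave 2297. The detected share as a covariate gave 1241, the experiment number across days 1114 and no background correction 145. A fit of the day 4 arrays alone gave 0 (1702 at an unadjusted p under 0.05), trend and robust moderation 44, leaving out the arrays with under 30% of probes detected 27, median scaling 2 higher and 733 lower, and scaling by mean and SD 329 and 418 (median shift -0.15). Without the AUF1 arrays of experiments 1 and 3 in turn the count was 36 and 0 (limma; 1341 at an unadjusted p under 0.05), and without the IgG arrays of experiments 1, 2, 3 and 4 it was 6, 377, 30 and 37.

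On day 6 limma called 0 probes between AUF1 and IgG, with 132 at an unadjusted p under 0.05 (0.956% of those tested). The median absolute difference was 0.14 log2 units on day 6, against 0.26 on day 0, 0.39 on day 2 and 0.34 on day 4. With the replicate block the count stayed at 0, with 742 at an unadjusted p under 0.05, and array weights gave 60. The difference on day 6 was not shown to depart from that on day 0: the test of day 6 minus day 0 called 0 probes (341 at an unadjusted p under 0.05; 0 and 1553 with the block; 4 with array weights), and the test of any difference between days called 0 (360; 0 and 2319 with the block; 36 with array weights).

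Across the 13812 probes, which are not independent replicates, the AUF1 minus IgG differences of days 0, 2 and 4 correlated with each other at r = 0.73 (days 0 and 2), 0.76 (days 0 and 4) and 0.71 (days 2 and 4). With day 6 they correlated at 0.47, 0.46 and 0.44. All 20 probes lower on day 0 were also called lower on day 2, where 0.31 would be shared by independent lists, and 16 of them on day 4 (0.083). Days 2 and 4 shared 39 lower probes (0.883 by independent lists) and 11 higher ones (0.22). Of the 294 probes called on day 2, 269 had the same sign on day 6. The days share 1 spread per probe, so probes with a small spread may be called on several days. Independent lists are therefore only a rough guide. AUF1 arrays were also dimmer than IgG arrays on every day, so a brightness trend could give such overlaps and correlations.

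Input RNA showed how the transcriptome changed as the cells differentiated. By day 3, 5148 of 13750 probes had changed (37.4%), 2361 rising and 2787 falling, and 1921 of them changed by at least 2-fold (977 up, 944 down). ILMN_1223735 rose from 5.42 ± 1.30 (log2, SD, n = 5) to 12.41 ± 0.82 (n = 5), a change of 6.99 ± 0.49 (SE; limma adjusted p = 1.1e-08), and ILMN_2882658 rose by 6.69 ± 0.65 (adjusted p = 3.6e-07). ILMN_2875585 fell from 13.38 ± 0.30 to 6.96 ± 0.56, a change of -6.42 ± 0.28 (adjusted p = 6.4e-11), and ILMN_2996648 changed by -6.26 ± 0.21 (adjusted p = 4.0e-12). On day 0 ILMN_1223735 was detected on 3 of 5 arrays and ILMN_2882658 on 4 of 5. Under median scaling 1485 rose and 2775 fell.

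By day 6, 5835 probes had changed against day 0 (42.4%), 2677 rising and 3158 falling, with 1151 up and 1145 down by at least 2-fold. ILMN_1260428 rose by 7.09 ± 0.37 (log2, SE; limma adjusted p = 2.8e-10), having been detected on 2 of 5 day 0 arrays, and ILMN_1223735 by 7.06 ± 0.49 (adjusted p = 6.9e-09). ILMN_2875585 changed by -7.51 ± 0.28 (adjusted p = 7.6e-12) and ILMN_2996648 by -7.19 ± 0.21 (adjusted p = 3.8e-13). The changes of days 3 and 6 went the same way: 2063 probes rose and 2503 fell on both days, and 0 were called in opposite directions. Independent lists would share 459.7 and 640.1. Both comparisons used the same day 0 arrays; when these were divided between them, 1264 to 1470 probes rose and 1508 to 1740 fell on both. The log2 changes correlated across probes at r = 0.97, against 0.51 simulated with no effect and 0.83 to 0.92 with divided day 0 arrays, and their covariance was 0.739 against 0.0245 simulated.

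**Figure D3:**
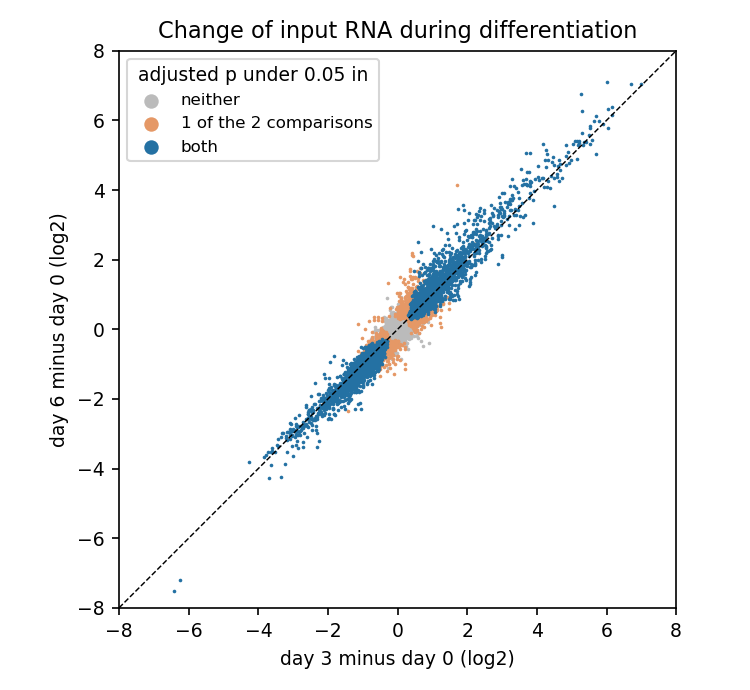
Log2 change of each of 13750 probes in input RNA from day 0 to day 3 (horizontal axis) and from day 0 to day 6 (vertical axis), coloured by whether it was called in neither, in 1 or in both comparisons; the dashed line marks equal change. The points lie along the line (r = 0.97), with 2063 probes rising and 2503 falling on both days.

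From day 3 to day 6, 62 probes changed in input RNA, 58 rising and 4 falling. ILMN_2915833 rose by 1.94 ± 0.14 (log2, SE; limma adjusted p = 1.1e-06) and ILMN_1245118 by 1.93 ± 0.22 (adjusted p = 0.000254); on day 0 neither was detected on any of the 5 arrays. ILMN_2714031 changed by -1.22 ± 0.26 (adjusted p = 0.0461), from 11.92 on day 0 to 10.86 on day 3 and 9.64 on day 6. ILMN_2859619 changed by -0.93 ± 0.20 (adjusted p = 0.0457) after standing at 4.88 on day 0 and 7.88 on day 3. These falling probes lost their calls under 15 and 13 of 21 alternatives (adjusted p up to 0.146 and 0.140), while the rising ones kept theirs under all 21. Of the 58 that rose, 30 had also risen by day 3. Median scaling called 22 and the test without a detection filter 40, while array weights called 128, 99 rising and 29 falling. Without input arrays 43 and 46 of day 3 the count was 37 and 36, and without arrays 41, 44 and 47 of day 6 it was 37, 37 and 35.

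AUF1 pulldown RNA was also set against input RNA of the same day. Pulldown arrays carry array numbers from 1 to 32 and input arrays from 33 to 47. A difference between these series of arrays therefore cannot be told apart from the pulldown. On day 0, 6438 of 14005 probes differed (45.97%), 3134 higher and 3304 lower in the pulldown; on day 6 it was 6684 (47.7%), 3376 higher and 3308 lower. ILMN_2882658 was higher in the day 0 pulldown, at 10.87 ± 0.20 (log2, SD, n = 4) against 6.35 ± 2.03 (n = 5) in input (limma adjusted p = 2.7e-05), and ILMN_2460136 by 4.01 ± 0.73 (SE; adjusted p = 0.000253). ILMN_2918479 differed by -6.59 ± 0.72 (adjusted p = 1.4e-06) and ILMN_2694960 by -5.65 ± 0.46 (adjusted p = 7.9e-08), and they were detected on 2 and 1 of the 4 AUF1 arrays. On day 6 ILMN_2789692 was higher by 4.39 ± 0.27 (adjusted p = 1.1e-09) and ILMN_2675833 by 4.35 ± 0.31 (adjusted p = 5.6e-09). Between day 0 and day 6 their input means fell from 7.14 to 4.80 and from 8.49 to 4.96. Their pulldown means went from 8.31 to 9.19 and from 9.52 to 9.32. The probes named as higher on day 0 stood below input on day 6. ILMN_2882658 was at 12.43 against 13.51 in input, and ILMN_2460136 at 12.87 against 13.46. ILMN_2918479 and ILMN_2694960 were again lower, with -5.91 ± 0.72 (adjusted p = 2.5e-06) and -5.55 ± 0.46 (adjusted p = 3.0e-08), being detected on 3 and 2 of the 4 AUF1 arrays. The days, which share no arrays here, had 1770 higher and 2013 lower probes in common (755.5 and 780.4 by independent lists), and 240 were called in opposite directions. Median scaling gave 499 higher and 5367 lower on day 0 (median shift -0.46) and 1259 and 3752 on day 6 (median shift -0.20), with 6298 of 6438 and 6683 of 6684 probes keeping their direction relative to the shift; the detected share as a covariate gave 3145 on day 0.

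The same comparison was made for the IgG control, an addition chosen after the data were examined, in a normalization of AUF1, IgG and input arrays together. On day 0 AUF1 pulldown differed from input at 6139 of 14632 probes and IgG pulldown at 5066, and 3946 of these were shared in the same direction (64.3% of the AUF1 calls; 1064 by independent lists). On day 6 it was 6403 and 6091 probes, with 5400 shared (84.3%; 1333 by independent lists). The log2 differences correlated across probes at 0.88 on day 0 and 0.97 on day 6, against 0.44 and 0.46 simulated with no effect. With the input arrays divided between the comparisons, the correlation was 0.77 to 0.85 on day 0 and 0.91 to 0.96 on day 6. The shared percentage was then 35.8% to 69.8% on day 0 and 65.3% to 89.2% on day 6. The covariance was 0.784 on day 0 and 1.11 on day 6, against 0.0426 and 0.0443 simulated.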

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

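The tests of explanations in this part were chosen after the patterns they address were seen, and the share of probes that keep their call with the detected share as a covariate and the spread of arrays and of differences on days 0 and 6 were known before their limits were set; the splits of the arrays were planned. Within groups of 4 or 5 arrays, 9 values out of 86 groups tested stood apart from the rest of their group by Dixon's criterion, where chance gives about 4.3. The IgG array of experiment 2 on day 4 had 25.6% of probes detected, against 43.5% to 46.8% on the other 3 arrays, and the IgG array of experiment 3 on day 6 had 35.7%, against 45.2% to 45.8%. The former array also stood apart for ILMN_2942573, at 7.52 (log2) against 5.31 to 5.38, and for ILMN_1215893, at 4.74 against 6.48 to 6.82. ILMN_2901944 was at 7.999 on the IgG day 0 array of experiment 4 and at 10.73 to 10.98 on the others. ILMN_2730425 was at 10.74 on the AUF1 day 6 array of experiment 4 and at 9.79 to 9.87 on the others. ILMN_2714031 was at 9.77 on input day 3 array 40 and at 10.95 to 11.25 on the others. ILMN_2882658 was at 10.56 on the AUF1 day 0 array of experiment 1, in the normalization with input, and at 10.94 to 10.99 on the others. ILMN_2694960 was at 7.16 on the AUF1 day 0 array of experiment 4 and at 4.39 to 4.78 on the others.

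Over the 4 days 2919 probes differed between AUF1 and IgG, and AUF1 arrays were also dimmer. With the detected share of each array as a linear covariate, 52.8% of these probes (1540) kept their call and direction among 3211 called in that fit (1634 higher, 1577 lower, against 1288 and 1631 without it), and over all 2919 a median of 79.8% of the difference was left, the median size going from 0.61 log2 units (SE 0.16) to 0.48 (SE 0.17). These 1540 calls remained with a linear term for the detected share. They were set apart by that outcome, so it is no separate test of such an effect on them. The limit for the 52.8% was set after it was known, and an effect that is not linear was not tested. Whether the dimmer arrays are the whole cause therefore stays undecided. The other 1379 lost their call because their differences shrank from a median of 0.54 (SE 0.16) to 0.26 (SE 0.15), leaving 52.2%; these probes were set apart by that outcome, so their sizes only describe them, and for them the dimmer arrays and the antibody cannot be told apart, since AUF1 arrays were the dimmer ones on every day. The slope on detected share within groups correlated with the AUF1 minus IgG difference at r = -0.282 across all tested probes and -0.404 across the 2919, between the limits set for a brightness trend and for none, so such a trend stays open. Every IgG array also carries an odd array number and every AUF1 array an even one. An effect tied to the array number therefore cannot be told apart from the antibody, for any of these probes or for the dimness. Binding of RNA by AUF1 stays open as an untested biological explanation.

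No probe was called between AUF1 and IgG on day 6 (132 at an unadjusted p under 0.05 in limma), and this was set against the other days with 1360 probes chosen on days 2 and 4 alone, 559 higher and 801 lower in AUF1. Their mean difference in the direction of days 2 and 4 was 0.76 ± 0.28 (log2, SD, n = 4 pairs) on day 0 and 0.25 ± 0.22 (n = 4) on day 6, or 32.6% of day 0 (two-sided exact permutation p = 0.0571; the smallest possible is 0.0286), so a difference as large as on day 0 is not excluded. The SD of the differences across the 13812 probes, which holds both the antibody differences and the spread, was 0.24 on day 6 and 0.45 on day 0, or 53.5% (exact permutation of the pairs, two-sided p = 0.0857; the smallest possible is 0.0286), and leaves this open too. A larger spread on day 6 was not seen, the median SD within groups being 90.1% of that on day 0, but it is not excluded, since the value ran from 82.2% to 102.8% without any 1 array and passed 100% without the AUF1 day 0 array of experiment 2; limma used 1 spread per probe for all days. The lowest of the 4 day 6 pairs was 0.070, above 0. None reached -0.38, the limit set for an exchange of AUF1 and IgG labels in an experiment. That limit was taken from the day 0 mean. With a difference as small as the 0.25 of day 6, an exchanged pair need not reach it, so an exchange is not excluded. The AUF1 minus IgG gap in detected share was also smallest on day 6, at -3.19 percentage points. It was -5.29 on day 0, -11.5 on day 2 and -7.77 on day 4. A smaller gap in brightness therefore stays open for the smaller differences of day 6. A weaker recovery of AUF1-bound RNA late in differentiation, in the cells or on the beads, stays open too, and neither was tested.

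The arrays were also split in other ways into groups of the same sizes. For the mean of 4 days, 1 of 100 splits within days, the real one, gave as many calls (2919; highest other 196), so chance can be excluded; among 100 arrangements that exchange AUF1 and IgG within pairs of the same day and experiment, the real one gave the most and the next 1649. For day 0, 2 of 35 splits reached the real 20 and chance cannot be excluded; the highest other, 453, points to a structure of the arrays and put the IgG array of experiment 4 with the AUF1 arrays of experiments 1, 3 and 4, while the 7 other splits that part all 4 pairs gave 0. Day 2 has 10 splits, too few for a share under 0.05, with 294 in the real one and 1 in the highest other, and 0 in the 3 others that part every pair. For day 4, 4 of 35 splits reached 95 and chance cannot be excluded; the highest other gave 1878, many times the real count, and points to a structure of the arrays, since its groups had 27.6% and 43.7% of probes detected on average. For day 6 the real count is 0, which all 35 splits reach of necessity, so their count says nothing about chance; the highest, 27, set experiments 1 and 2 against 3 and 4, and with the experiment as a block the real count was 0. For day 6 minus day 0 and for any difference between days, the real counts are also 0, all 100 splits reach them of necessity, and nothing is said about chance (341 and 360 probes had an unadjusted p under 0.05 in limma). The highest splits gave 620 and 28, which points to a structure of the arrays. For input on days 3 and 6 against day 0, 1 of 100 splits each, the real one, reached 5148 and 5835, against 1319 and 1406 in the highest others, so chance can be excluded. For input on day 6 against day 3, 6 of 100 splits reached 62 and chance cannot be excluded; the highest, 445, set arrays 34, 35, 37, 38 and 41 against 40, 43, 44, 46 and 47, nearly by array number, which points to a structure of the arrays, and with sets of 3 array numbers as a block the real count was 86. For AUF1 against input, 1 of 100 splits each, the real one, reached 6438 and 6684, against 4849 and 4394 in splits that moved 1 input array to the AUF1 side. A chance division of these arrays can be excluded, but not a difference between the array series of pulldown and input. Wherever chance was excluded here, this holds for these arrays alone, since the labels do not say that they come from separate cultures.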

How the results depend on the processing

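The covariate, array weights, blocks across days or sets of arrays, and the omission of dim arrays were chosen after seeing the data. Counts within 1.5 times of those reported were found for input on days 3 and 6 against day 0 and for AUF1 against input on day 6 under every alternative run, and for AUF1 against input on day 0 under all except the detected share as a covariate, which gave 3145. Signal over background limits which probes could be tested, 13812 of 25697 in the pulldown comparisons. Where a count moved further, the cause was not tested, except that a fit of only the groups compared uses fewer arrays.

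Under median scaling the counts were 6780 for the mean of 4 days, 0 for day 0, 2141 for day 2, 735 for day 4 and 22 for input on day 6 against day 3. Scaling by mean and SD gave 1368 on day 2 and 747 on day 4, no background correction 58 on day 0 and 145 on day 4, trend and robust moderation 44 on day 4, and no detection filter 40 for input on day 6 against day 3. Fits of only the groups compared called 0 on day 0, 28 on day 2 and 0 on day 4. In limma the counts of 0 on day 0 (median scaling, only the groups compared) and day 4 had 1817, 1716 and 1702 at an unadjusted p under 0.05. Under median scaling ILMN_1215893 on day 4 turned to -0.077 (limma adjusted p = 0.911; range over alternatives 0.00188 to 0.911), a shift common to the probes, whose median moved by -0.73; relative to it all 95 called on day 4 kept their direction.

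The experiment number as a replicate block gave 6538 for the mean of 4 days, 1764 on day 0, 3614 on day 2 and, where the numbers were not taken as pairs, 3398 on day 4; it moved no other count by over 1.5 times, giving 5145, 5888 and 78 for the input comparisons and 6010 and 6526 for AUF1 against input. As a block across days it gave 4666, 708, 1870 and 1114 for the mean and days 0, 2 and 4. The detected share as a covariate gave 72, 635 and 1241 on days 0, 2 and 4. Array weights gave 6076, 1133, 2642, 2297 and 60 for the mean and days 0, 2, 4 and 6, 4 for day 6 minus day 0, 36 for any difference between days and 128 for input on day 6 against day 3. Without arrays under 30% detected, 0 (1881 unadjusted, limma) were called on day 2, where 1 AUF1 array was left and is assumed to vary like the other groups, and 27 on day 4, with 2 AUF1 and 3 IgG arrays left.

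Leaving out 1 array at a time, counts ran from 2135 to 3961 for the mean of 4 days, 1 to 223 on day 0, 0 to 692 on day 2 and 0 to 377 on day 4, and stayed at 0 on day 6 and for both tests between days. They ran from 4543 to 5497 and 5273 to 6142 for input on days 3 and 6 against day 0, 35 to 60 for day 6 against day 3, and 5700 to 6745 and 6054 to 6772 for AUF1 against input. Of the probes named, those of input against day 0 and of AUF1 against input kept direction and call throughout. Blocking by slide, averaging the probes of 1 gene, and the gene lists with their set tests were not run.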

Other observations

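The comparisons of pulldown RNA over time, of IgG pulldown with input and of array positions were chosen after the data were examined, and their tests were set out before their values were known, except for the array positions. RNA recovered with the control antibody changed during differentiation along with the cell's RNA. From day 0 to day 6, 262 probes rose and 52 fell in IgG pulldowns; 204 of the former had risen and 42 of the latter had fallen in input, and 6 went against it. In AUF1 pulldowns 569 rose and 458 fell, 320 and 225 of them with the input and 77 against it. Probes that rose in input (2446 measured in both) had a median input change of 0.92 (log2), a median change of 0.25 in IgG and 0.27 in AUF1 pulldowns; for the 3020 that fell the medians were -0.85, -0.18 and -0.11.

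Across 12511 probes, which are not independent replicates, the IgG change correlated with the input change at r = 0.537, and the AUF1 change at 0.408, from separate arrays. This fits the hypothesis that RNA recovered with either antibody may carry much of the cell's RNA. The overlap of AUF1 and IgG calls against input, taken alone, leaves a related hypothesis open, that the same RNAs differ from input with either antibody. On day 6, 84.3% of the AUF1 calls were made the same way with IgG, and on day 0 64.3%, but both comparisons used the same input arrays. With these divided between them the percentage ran from 65.3% to 89.2% on day 6 and from 35.8% to 69.8% on day 0. The log2 differences then still correlated across probes at 0.91 to 0.96 on day 6 and 0.77 to 0.85 on day 0. Across probes, the AUF1 and IgG arrays thus departed from the input arrays largely in the same way. Since pulldown and input arrays form separate series by array number, a difference between the series would give the same result. It cannot be told apart from the pulldown.

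A further hypothesis was that RNAs rising during differentiation may be recovered by AUF1 to another extent than RNAs that fall. It stays undecided, since the probes of each set went both ways (42.5% of the risers and 46.7% of the fallers were higher in AUF1) and medians near 0 then decide nothing: the median AUF1 minus IgG difference of the risers minus that of the fallers was -0.028 (log2), and camera gave p = 0.14 for risers and 0.888 for fallers (0.337 and 0.946 with an estimated correlation; 0.28 and 0.888 adjusted over the 2 sets). For the fallers the median, -0.033, lay below that of the other probes, -0.0049, while camera's direction was upward; for the risers both were downward. Of the risers 8.26% were called higher and 13.9% lower in AUF1, of the fallers 11.1% and 11.6%, and of the other probes 8.99% and 11.3%.

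The input arrays of day 0 spread more widely than those of later days. On a scale from the mean of day 0 (0%) to the mean of day 6 (100%), over the probes that changed between them with the array in question left out, the day 0 arrays 33, 36, 39, 42 and 45 lay at -8.14%, -11.2%, 11.5%, 2.04% and 23.2%, with an SD of 14.2 (n = 5). The 5 day 3 arrays lay at 88.9% ± 6.11 (SD, n = 5), between 81.3% and 96.9%, and the day 6 arrays at 97.6% ± 3.99 (SD, n = 5). ILMN_2882658, which rose to 13.20 by day 3, was at 5.07, 4.51, 7.62, 5.75 and 9.61 on these day 0 arrays, in the same order; this probe was looked at in single arrays after its values were seen.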
